A study of Homo sapiens with 6 samples.

How the data were processed

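Gene expression was measured with Illumina HT-12 bead arrays, on which each probe is read as the mean brightness of many beads. Total RNA was extracted and turned into biotin-labelled cRNA, per the labels' protocols, and 6 samples were hybridised. The titles name 3 samples of O4-sorted cells and 3 of undifferentiated human embryonic stem (hES) cells. The sample labels give the H9 line, and the series description gives day 70 for the sorted cells. The titles call the samples of each group biological replicates. Nothing in the sources used here says whether they came from separate cultures, so p-values measure the spread between these samples, which may in part be technical.

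The authors deposited a table of probe intensity that had not been normalized, on a linear scale, with the bead number and bead standard error of each probe, per the file headers. The same deposited table holds a detection p-value per probe and array, which states how often control beads without a target were as bright. The smallest p-values step in units that correspond to 770 control probes. GenomeStudio is named as the software, per the submitters' processing notes, and its version is not given in the sources used here. A second deposited table holds processed intensity values of 47321 probes, and its steps are not given in the sources used here. Within each array its values ranked the probes exactly as the unprocessed signal did (Spearman correlation 1, across probes), and 29.6% of its values lay below 0. Its scale is therefore taken as linear after background subtraction. The column medians were 6.57, 6.60 and 6.58 for O4-sorted replicates 1 to 3 and 6.62, 6.63 and 6.61 for undifferentiated replicates 1 to 3. The highest unprocessed signal was 21604.7, on O4-sorted replicate 2, and the highest processed value on any array was 17188.9. The median of that replicate fell only from 113 to 6.60. A step that changed the scale was therefore applied besides background subtraction. Its kind stays unknown, and this table served only as an alternative. No column of another sample was present (0 columns).

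Of the 47322 probes, 30113 were named with 1 gene through the 2016 platform annotation, 8 had several genes and 17201 were unnamed here. Symbols of 30074 probes were checked, and updated where they differed, through their gene ID with the RefSeq genes of the GRCh38.p14 assembly. The genome build behind the array design is not named in the sources used here, so no coordinates are given.

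Background was corrected and arrays were normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normal plus exponential model with the background inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. The offset pulls the fold changes of dim probes towards 1. A probe counted as detected at a detection p-value under 0.01, and 14877 probes detected on at least 3 of the 6 arrays were kept. Each gene was represented by its brightest probe over all 6 arrays, chosen without regard to group, and unnamed probes were tested as features of their own, which gave 12267 features. Of these, 9626 were named genes. Among 2211 genes with more than 1 probe tested, 37 (1.67%) had probes called in opposite directions. The brightest probe can overstate a gene: the weakest probes of FGF2, TET1, OTX2, KCNIP1, LSS, PDGFRA and TAGLN3 gave log2 fold changes of -0.99, -1.08, -1.92, 1.96, 1.27, 2.76 and 3.89, against -3.31, -3.27, -3.32, 3.70, 2.22, 4.16 and 5.81 for the tested ones.

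Groups were compared with limma's lmFit and eBayes on log2 values, as O4-sorted minus undifferentiated, with no covariate. Unless an alternative is named, adjusted p-values of genes come from this model, two-sided, with Benjamini-Hochberg adjustment over the 12267 features and a threshold of 0.05. The fit had 4 residual and 4.89 prior degrees of freedom. Errors given after a log2 fold change are the model's standard errors (SE). Where a probe was not detected on all 3 arrays of the dimmer group, its fold change is given as "at least N-fold". This sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the lowest normalized value among detected probes or the probe's own value, whichever was higher. Where this gave no fold above 1, no fold is printed, and the member enters the bounded median of its list as 0. Those medians replace only members detected on no array of a group. Bounds of probes detected on some arrays of the dimmer group were added after the values were seen.

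Gene lists, 32 in number with 838 members, were fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives, unless stated otherwise. Lists with at least 3 tested members (30 lists) were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and fry were alternatives. Medians of lists are also given with undetected members at their bound. Genes were named by a fixed rule with 4 parts. Part 1 took the 8 largest rises and 8 largest falls among genes past the threshold, detected on all 6 arrays and with groups that did not overlap. Part 2 took the 5 largest bounds per direction, and part 3 a set of 17 pluripotency, oligodendrocyte and astrocyte genes. Part 4 took up to 3 rises and 3 falls per list. Members of small counts that fall outside the rule are named as chosen after their values were seen.

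The descriptions of undifferentiated replicates 1 and 3 share a name, whereas their titles number them separately. Their log2 signals differed by an SD of 0.228 over 13345 probes, 1.28 times what the bead standard errors give, and no probe held identical values (0 probes). The other pairs of undifferentiated arrays differed by 1.65 and 1.71 times the bead noise. The pair was kept as separate replicates, and an alternative counted it as 1 sample.

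The pipeline was tested on simulated arrays with a detection step, in which 200 genes were changed between the groups. Signal levels of both groups came from the undifferentiated arrays. The noise of each probe was drawn at random from the SDs within groups of the kept probes, whatever its brightness. Background noise was added on top, so the simulated noise need not match the measured noise. Of 15270 features tested there, 2 of 15076 unchanged ones were called. Among changed genes that were tested, 94.0% were recovered at 8-fold, 87.5% at 4-fold, 17.0% at 2-fold and 0 of 49 at 1.5-fold. The median estimated fold was 6.13 at 8-fold and 3.26 at 4-fold. With no gene changed, 0 genes and 0 of 32 lists were called. With 1 list raised 2-fold, that list was called (1 of 1) and 0 others were. Simulated noise was drawn independently for each probe, so the list results do not test camera on genes that vary together. In the measured data the estimated correlation ran from -0.226 in the microglia and blood list to 0.487 in the forebrain and midbrain list. The recovery shares need not carry over either, as 69.4% of the measured features were called.

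The alternatives were no background correction, scaling to the 75th percentile, cyclic loess, an offset of 50, the authors' processed values, no detection filter, detection on all 6 arrays, a detection p-value under 0.05, the mean of a gene's probes, all probes as features, robust trended moderation, array weights, the replicate number as a block and each replicate left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.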

Results

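The study measured gene expression in oligodendrocyte-lineage cells made from H9 hES cells and in the undifferentiated cells themselves, with 3 arrays per group. H9 is an established human embryonic stem cell line. O4 is an antibody that binds sulfatide and related lipids on the surface of late oligodendrocyte progenitors and oligodendrocytes, and the differentiated cells had been sorted for it at day 70. Each array held 47322 probes with a median of 21 or 22 beads per probe. O4-sorted cells had 11347, 13336 and 12113 detected probes, a mean of 12265 ± 1003 (SD, n = 3). Undifferentiated cells had 14713, 15824 and 14366 detected probes, a mean of 14968 ± 762 (SD, n = 3). The groups did not overlap, and an exact permutation test, two-sided, gave p = 0.1, the smallest value that 3 against 3 arrays allow. The number of arrays limits the precision of every value given here.

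The comparison asks how the expression of O4-sorted cells differed from that of the undifferentiated cells they were derived from. Most tested genes of oligodendrocyte progenitors and of myelin rose in the sorted cells, while most of the pluripotent state, of epithelial cell contacts and of cell division fell. As lists, only the pluripotency genes passed at adjusted p = 0.0348 with an estimated correlation, against 0.180 and 0.0925 for progenitor and myelin genes, 0.0692 for epithelial genes and 0.277 and 0.297 for the cell cycle lists. OLIG2, OLIG1 and SOX10, which specify and maintain the oligodendrocyte lineage, were detected on all 3 sorted arrays and on no undifferentiated array, and were at least 174-fold, 123-fold and 119-fold higher. LIN28A, an RNA-binding protein of pluripotent cells, and DNMT3B, a de novo DNA methyltransferase, showed the opposite pattern and were at least 97.6-fold and 81.1-fold lower. The DNMT3B bound is that of its brightest probe, and its 4 probes gave log2 fold changes from -6.95 to -1.33.

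Of the 12267 features tested, 3951 were higher and 4568 were lower in O4-sorted cells, and 3748 did not pass the threshold. A change of at least 2-fold was reached by 2412 of the higher and 2705 of the lower features, and a change of at least 8-fold by 319 and 283. The median log2 fold change of all features was -0.09. In 8968 features (73.1%) the groups did not overlap, where chance gives 10%. On all sorted arrays but no undifferentiated array, 542 features were detected, and 1574 showed the reverse. The lowest normalized log2 value among detected probes was higher on the sorted arrays, at 5.69, 5.30 and 5.52 for replicates 1 to 3. On undifferentiated replicates 1 to 3 it was 5.12, 5.02 and 5.16. Detection was therefore not evenly matched between the groups, and its part in these counts was not tested. Counts at 2-fold depended on the background step, with 1282 higher and 1270 lower when no background was subtracted. When only features detected on all 6 arrays were tested, 55.9% of the calls were higher, against 46.4% in the main comparison.

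Among genes measured on all 6 arrays, the largest rise was that of FABP7, the brain lipid-binding protein of radial glia, which was 213-fold higher (log2 fold change 7.74 ± 0.34 SE, adjusted p = 1.72e-07). TTYH1, a membrane protein of neural cells, was 80.7-fold higher, and TUBB4A, a brain beta-tubulin, was 67.9-fold higher. CLDN11, the claudin of myelin tight junctions, rose 50.9-fold (log2 5.67 ± 0.15 SE, adjusted p = 1.70e-08). FEZ1, FXYD6, GNG7 and TSPAN7 rose by 39.5-fold, 34.3-fold, 32.3-fold and 31.0-fold, where the 4 probes of FEZ1 ran from log2 2.36 to 5.30. The largest bound belonged to SCRG1, which was at least 210-fold higher, followed by BCAN, the brain proteoglycan brevican, at least 202-fold higher by the brightest of 3 probes, whose log2 fold changes ran from 1.51 to 7.98.

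The largest fall among genes measured on all 6 arrays was that of SNAR-A1, a small noncoding RNA, which was 57.6-fold lower (log2 -5.85 ± 0.23 SE, adjusted p = 1.06e-07). PODXL, a sialomucin of pluripotent cells, was 22.9-fold lower, and CCN2, a matricellular protein, 17.9-fold lower. MT1X, a metallothionein, was 19.7-fold lower. SNAR-A1 and MT1X have near-identical copies whose signal a probe can share, so these values are uncertain as to the gene. RASL11B, SPINT2, MTHFD2 and TAGLN were 17.3-fold, 15.6-fold, 15.5-fold and 14.8-fold lower. ACTA1, skeletal muscle actin, was detected on all undifferentiated arrays and no sorted array and was at least 86.4-fold lower.

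**Figure D1:**
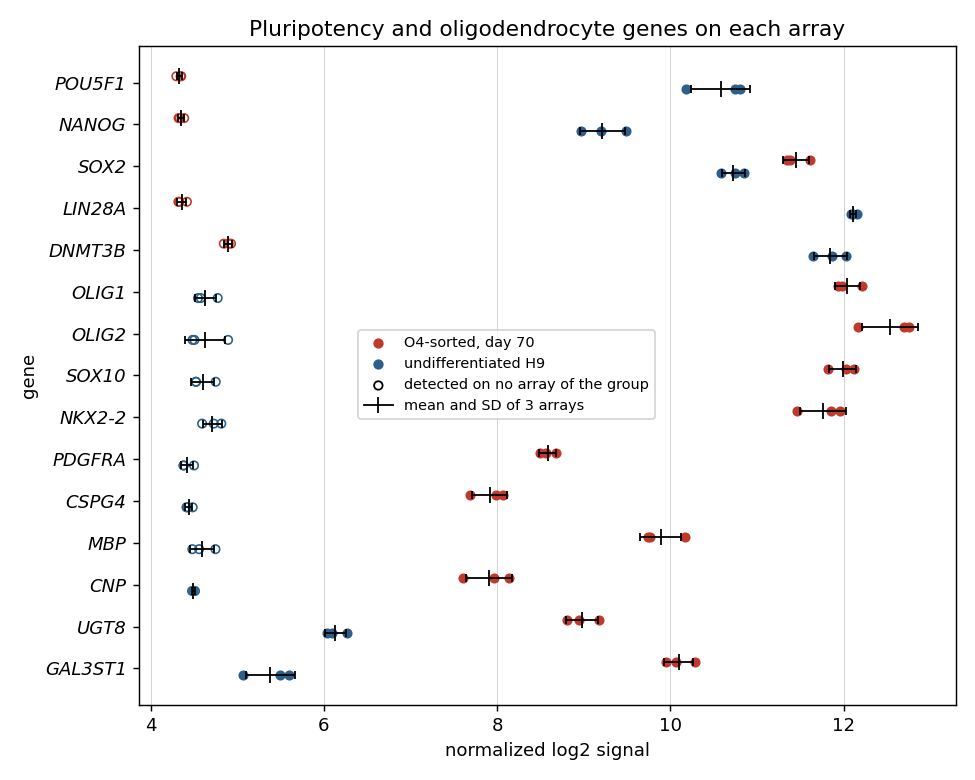
Normalized log2 signal (x axis) of 15 pluripotency and oligodendrocyte genes (y axis) on each of the 6 arrays, with a point per array, the mean and SD of each group of 3, and open points where the probe was detected on no array of that group. The groups are separate for every gene shown, and SOX2, with means of 11.45 and 10.73, is the only pluripotency gene of the plot that is higher in O4-sorted cells.

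Pluripotency genes were lower almost throughout. Of 29 tested members, 28 fell and 1 rose, with a median log2 fold change of -4.41, or -3.71 with undetected members at their bound (camera adjusted p = 3.93e-12). The list stayed past the threshold with an estimated correlation (adjusted p = 0.0348). L1TD1, an RNA-binding protein, and ZFP42, a zinc finger protein, both used as markers of pluripotent cells, were at least 70.1-fold and 53.4-fold lower. POU5F1 and NANOG, core transcription factors of pluripotency, were at least 33.7-fold and 13.1-fold lower, with the limit that both genes have near-identical pseudogene copies. SOX2, which is active in pluripotent and in neural progenitor cells, was the member that rose, by 1.65-fold (log2 0.72 ± 0.15 SE, adjusted p = 0.00219).

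The oligodendrocyte progenitor list moved the other way. Of 30 tested members, 28 rose, 1 fell and 1 did not pass, with a median of 3.998, or 3.55 with undetected members at their bound (camera adjusted p = 1.14e-12; adjusted p = 0.180 with an estimated correlation). Another 12 of the 42 members named on the array were not detected on enough arrays to be tested. NKX2-2, a transcription factor of oligodendrocyte differentiation, was at least 101-fold higher. The progenitor surface markers PDGFRA and CSPG4, the latter known as NG2, were at least 11.2-fold and 7.02-fold higher. VCAN, a large matrix proteoglycan, was the member that fell (log2 -1.32), and SERPINE2 did not pass the threshold (log2 -0.22), the latter named after its value was seen.

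All 21 tested members of the myelin list rose, with a median of 2.85, or 2.80 with undetected members at their bound. The list gave camera adjusted p = 9.72e-10, and 0.0925 with an estimated correlation. A further 10 of the 31 members named on the array were not detected on enough arrays to be tested. SIRT2, a deacetylase abundant in oligodendrocytes, was at least 107-fold higher, and MAG, an adhesion protein of the inner myelin layer, at least 97.3-fold higher, though another MAG probe gave a log2 fold change of 1.70. UGT8 and GAL3ST1, the enzymes that make galactocerebroside and sulfatide, rose 7.19-fold (adjusted p = 6.06e-07) and at least 25.9-fold (adjusted p = 9.52e-08). CNP, a phosphodiesterase of non-compact myelin, was at least 6.99-fold higher. The tested probe of MBP, a major protein of compact myelin, was at least 27.7-fold higher. Another MBP probe, detected on all undifferentiated arrays, gave a log2 fold change of -0.30. That probe did not pass in the alternative limited to features detected on all 6 arrays (adjusted p = 0.232). GFAP, an astrocyte filament protein, was detected on 2 sorted arrays and 0 undifferentiated arrays and was not tested.

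Enzymes of cholesterol synthesis, a lipid that myelin holds in large amounts, were higher. Of 18 tested members, 14 rose, 0 fell and 4 did not pass, with a median of 1.07 (camera adjusted p = 0.000119; adjusted p = 0.180 with an estimated correlation). MVK, mevalonate kinase, was at least 4.82-fold higher, TM7SF2, a sterol reductase, rose 5.86-fold, and LSS, lanosterol synthase, rose 4.67-fold. In the lysosome and lipid handling list, 11 of 25 members rose, 4 fell and 10 did not pass (median 0.40, camera adjusted p = 0.129). ABCA2, a lipid transporter abundant in oligodendrocytes, was at least 6.85-fold higher, and APOE, a lipid carrier, was at least 13.6-fold lower.

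Genes of other neural cells also moved with the sorted group. In the neuron list, 17 of 21 tested members rose, 2 fell and 2 did not pass, with a median of 2.12, or 1.87 with undetected members at their bound (camera adjusted p = 2.01e-06; adjusted p = 0.180 with an estimated correlation). STMN2, a regulator of neuronal microtubules, TAGLN3 and DCX, a microtubule protein of young neurons, were at least 71.8-fold, 53.1-fold and 40.5-fold higher. SYT1, a synaptic vesicle calcium sensor detected on no sorted array, and NEFH, a neurofilament, were the members that fell, SYT1 by at least 1.14-fold and NEFH by at least 1.49-fold. In the neural stem and radial glia list, 14 of 18 rose, 2 fell and 2 did not pass, with a median of 2.67, or 2.27 with undetected members at their bound (camera adjusted p = 0.000424; adjusted p = 0.310 with an estimated correlation). HES5, a Notch target, was at least 53.2-fold higher. ASPM, a mitotic spindle protein, and PROM1, a surface protein of stem cells, were the members that fell, by at least 6.47-fold and by 3.12-fold.

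Of 13 tested astrocyte genes, 8 rose, 3 fell and 2 did not pass, with a median of 1.07, and the list did not pass the set test (camera adjusted p = 0.128). It did pass without O4-sorted replicate 3 (median 1.09, adjusted p = 0.0388), without a detection filter (adjusted p = 0.00685), at a detection p-value under 0.05 (adjusted p = 0.0315) and with fry (adjusted p = 0.00323). HEPACAM, a glial adhesion protein, and SOX9, a glial transcription factor, were at least 15.5-fold and 11.7-fold higher, and the glutamate transporter SLC1A3 rose at least 11.7-fold. SLC1A3 varied between the sorted arrays, with log2 signals of 9.08, 10.09 and 7.55 on replicates 1 to 3, so that leaving out replicate 3 gave a larger rise. GJA1, the gap junction protein connexin 43, was 13.5-fold lower. FGFR3 also fell (log2 -1.22, adjusted p = 0.0222), but not past the threshold without O4-sorted replicate 2 (adjusted p = 0.0629), without O4-sorted replicate 3 (adjusted p = 0.0783), without undifferentiated replicate 2 (adjusted p = 0.0781) or without undifferentiated replicate 3 (adjusted p = 0.0650). Its call was also lost without a detection filter (adjusted p = 0.110) and with undifferentiated replicates 1 and 3 as 1 sample (adjusted p = 0.0569). MLC1 was the third member that fell, detected on no sorted array and with no fold above 1 that could be bounded.

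Adhesion and guidance genes of neural cells were higher in 11 of 16 tested members and lower in 2, and 3 did not pass, with a median of 1.85, or 1.53 at the bound (camera adjusted p = 0.00139; adjusted p = 0.180 with an estimated correlation). The ephrin receptor EPHB1, the neuroligin NLGN3 and the neurexin NRXN2 were at least 33.6-fold, 21.1-fold and 20.03-fold higher. LRRN1 and SEMA6A were the members that fell (log2 -0.90 and -0.61), SEMA6A with adjusted p = 0.0150 and without undifferentiated replicate 1 or 2 with adjusted p = 0.0528 or 0.0502. Among ion channels and transmitter receptors, 8 of 10 rose, 1 fell and 1 did not pass, with a median of 1.97, or 1.76 at the bound (camera adjusted p = 0.00163; adjusted p = 0.211 with an estimated correlation). NKAIN4, which interacts with the sodium pump, and KCNIP1, a potassium channel partner, were at least 11.6-fold and 9.73-fold higher. GRIN1, an NMDA receptor subunit, was the member that fell (adjusted p = 0.00750). Its probe was detected on no sorted array, no fold above 1 could be bounded, and it did not pass under either other scaling (adjusted p = 0.0830 and 0.0665) or without background correction (adjusted p = 0.0580).

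**Figure D2:**
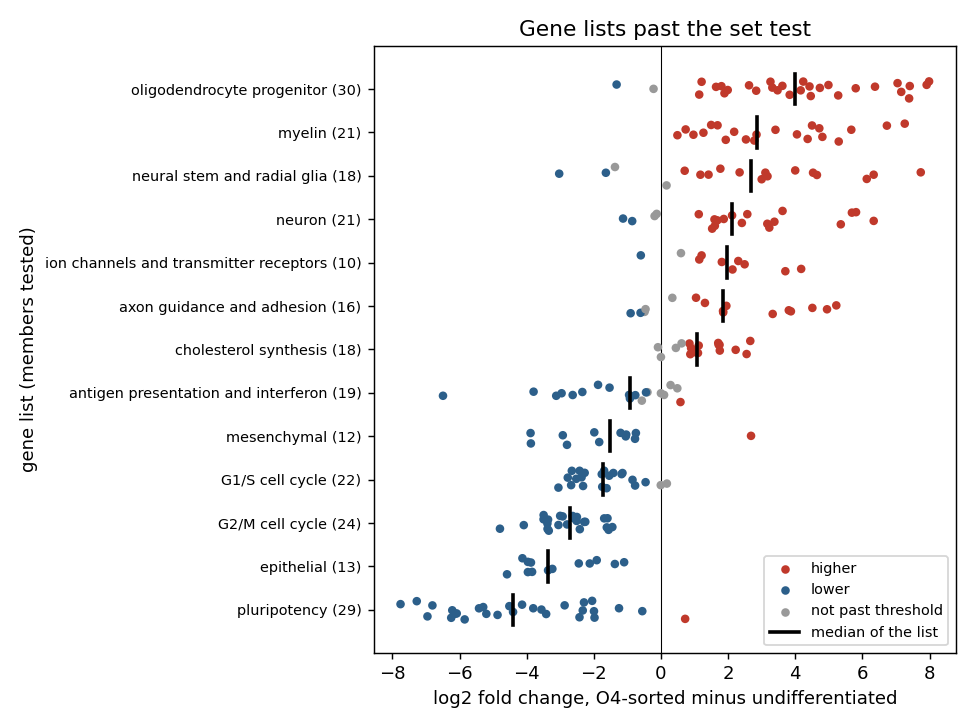
Log2 fold change of each tested gene, O4-sorted minus undifferentiated (x axis), in the 13 gene lists past the set test at the preset correlation (y axis, members tested in parentheses), with a point per gene coloured by its call and a bar at the median. Medians run from -4.41 in the pluripotency list to 3.998 in the oligodendrocyte progenitor list.

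Epithelial and dividing-cell genes fell. All 13 tested epithelial genes were lower, with a median of -3.36, or -2.42 with undetected members at their bound (camera adjusted p = 3.89e-07; adjusted p = 0.0692 with an estimated correlation). KRT19, a keratin, and the tight junction claudins CLDN6 and CLDN7 were at least 12.97-fold, 7.74-fold and 7.60-fold lower. Of 24 tested mitotic genes (the G2/M list), 24 fell, with a median of -2.71, or -2.55 with undetected members at their bound (camera adjusted p = 3.04e-08; adjusted p = 0.277 with an estimated correlation). DLGAP5 and BUB1, proteins of the mitotic spindle and its checkpoint, were at least 14.3-fold and 11.1-fold lower, and the DNA topoisomerase TOP2A was 11.3-fold lower. Of 22 genes of DNA replication (the G1/S list), 20 fell, 0 rose and 2 did not pass, with a median of -1.72 (camera adjusted p = 1.09e-05; adjusted p = 0.297 with an estimated correlation). The licensing factor CDT1 was at least 8.28-fold lower, and the helicase subunit MCM6 and geminin, GMNN, were 6.85-fold and 6.39-fold lower.

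Mesenchymal genes were lower in 11 of 12 tested members and higher in 1, with a median of -1.52, or -1.12 at the bound (camera adjusted p = 0.00260; adjusted p = 0.211 with an estimated correlation). S100A4 was at least 8.54-fold lower and MYL9, a myosin light chain, at least 4.46-fold lower. ACTA2, smooth muscle actin, was the member that rose, by 6.42-fold (adjusted p = 0.000147). Among genes of antigen presentation and interferon response, 12 of 19 fell, 1 rose and 6 did not pass, with a median of -0.92, or -0.57 at the bound (camera adjusted p = 0.00920; adjusted p = 0.353 with an estimated correlation). IFITM1, an antiviral membrane protein, was at least 42.6-fold lower and BST2 at least 6.40-fold lower. B2M, the invariant chain of MHC class I, was the member that rose (log2 0.58, adjusted p = 0.0140), though not past the threshold without undifferentiated replicate 3 (adjusted p = 0.0628). The mesenchymal, antigen presentation and adhesion lists lost their calls among features detected on all 6 arrays (adjusted p = 0.543, 0.343 and 0.802).

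The metabolic, stress, signalling and matrix lists given next, unlike the cholesterol list above, held members that went both ways. None of those given next passed the set test at the preset correlation and detection filter. Glycolytic genes fell in 10 of 18 members, rose in 3 and did not pass in 5 (median -0.58, camera adjusted p = 0.113). The glucose transporters SLC2A3 and SLC2A1 and lactate dehydrogenase A, LDHA, were 12.6-fold, 6.62-fold and 7.16-fold lower, and ENO2, the neuronal enolase, was 4.09-fold higher. Of 29 oxidative phosphorylation genes, 12 rose, 1 fell and 16 did not pass (median 0.25, camera adjusted p = 0.116). Of 35 ribosomal protein genes, 4 rose, 6 fell and 25 did not pass (camera adjusted p = 0.944), and the median of 0.01 and the upward test differed in sign from the mean of -0.01. The integrated stress response list had 4 higher, 9 lower and 6 not past of 19 (median -0.32, camera adjusted p = 0.202), with DDIT3 at least 4.65-fold higher and MTHFD2 lower as given above. Immediate early and dissociation stress genes rose in 7, fell in 5 and did not pass in 5 of 17 members (median 0.19, camera adjusted p = 0.513), with DUSP1 2.98-fold higher and IER3 at least 10.7-fold lower.

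In the FGF and TGF-beta family list, 4 of 17 members rose, 10 fell and 3 did not pass (median -1.11, camera adjusted p = 0.202), with FGF2, a growth factor for hES cells, at least 4.86-fold lower and ID2 9.81-fold higher. Wnt pathway genes rose in 5, fell in 4 and did not pass in 3 of 12 members (camera adjusted p = 0.857), and the median of -0.08 differed in sign from the mean of 0.14 and the upward test. APCDD1, a Wnt inhibitor at the membrane, was at least 50.3-fold higher and the tested probe of the receptor FZD7 was at least 20.6-fold lower, whereas its other probe gave a log2 fold change of -0.20. The retinoic acid list had 4 higher, 4 lower and 1 not past of 9 (camera adjusted p = 0.972), and the median of 0.22 differed in sign from the mean of -0.63 and the downward test. CYP26A1, which degrades retinoic acid, was at least 24.1-fold lower by the brightest of 3 probes (log2 -5.08 to -1.10), and TSHZ1 at least 6.91-fold higher. Extracellular matrix and integrin genes rose in 7, fell in 12 and did not pass in 5 of 24 members (median -0.82, camera adjusted p = 0.395). NCAN, the brain proteoglycan neurocan, rose at least 15.6-fold, and the laminin chain LAMA5 was 8.76-fold lower.

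Lists of other lineages had few tested members. Of 4 neural crest and Schwann genes, 3 rose and 1 fell (camera adjusted p = 0.304), with PMP2, a myelin lipid-binding protein, at least 18.3-fold higher. Of 4 endoderm and mesoderm genes, 2 rose, 1 fell and 1 did not pass (camera adjusted p = 0.513), with MESP1 at least 5.28-fold higher and AFP at least 4.69-fold lower. TTR, a thyroid hormone carrier, was at least 2.16-fold higher (adjusted p = 0.0138). It was not past the threshold without undifferentiated replicate 3 (adjusted p = 0.0562) or without a detection filter (adjusted p = 0.0791). Microglia and blood genes fell in 2 of 4 and did not pass in 2 (camera adjusted p = 0.213). Hedgehog genes rose in 2, fell in 1 and did not pass in 1 of 4 (camera adjusted p = 0.530). Of the choroid plexus and cilia list only OTX2 and CLIC6 were tested, too few for the set test, and OTX2 was at least 5.06-fold lower. CLIC6 fell too (adjusted p = 0.0419), was detected on no sorted array and had no fold above 1 that could be bounded. Its call was lost without O4-sorted replicate 2 (adjusted p = 0.0865) or 3 (adjusted p = 0.140), or undifferentiated replicate 1 (adjusted p = 0.0747) or 2 (adjusted p = 0.155), and also under both other scalings (adjusted p = 0.139 and 0.0883), without background correction (adjusted p = 0.103), at an offset of 50 (adjusted p = 0.0807), without a detection filter (adjusted p = 0.119) and with undifferentiated replicates 1 and 3 as 1 sample (adjusted p = 0.0593).

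Adjusted over the list alone, the counts higher and lower were the same as over all features in every list except 5. These were the FGF and TGF-beta family list (4 higher, 11 lower), the extracellular matrix list (8 higher, 12 lower), the oxidative phosphorylation list (11 higher, 1 lower), the ribosomal list (4 higher, 5 lower) and the antigen presentation list (1 higher, 13 lower). Of the 30 lists tested with camera, 7 passed upwards and 6 downwards, and 1 passed with an estimated correlation. With fry, which asks only whether the genes of a list move on balance one way, 24 passed.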

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

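The counts of higher and lower features stayed within 1.5 times the main counts under every alternative tried except those named here. Without background correction, 1282 features were higher and 1270 lower by at least 2-fold, a setting whose construction leaves the background in both terms of each fold. Among features detected on all 6 arrays, 2312 were lower, and 1544 were higher and 1172 lower by at least 2-fold, a setting that tests fewer features (7826) and removes those lost in 1 group. The oligodendrocyte progenitor and myelin lists kept their medians of 3.998 and 2.85. With an estimated correlation neither passed (camera adjusted p = 0.180 and 0.0925). Their estimated correlations were 0.181 and 0.0636, above the preset 0.01. A higher correlation is not the whole reason for weaker p-values under this alternative. The epithelial list, with an estimated correlation of -0.0155, went from an unadjusted camera p of 6.48e-08 to 0.00461. The pluripotency list, at -0.0287, went from 2.62e-13 to 0.00116. What else weakened them was not tested. Over the alternatives that refit the genes, the pluripotency list passed in all. MBP, whose tested probe was at least 27.7-fold higher, had a log2 fold change of -0.30 when detection on all 6 arrays was required, because another of its probes then stood for the gene.

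Leaving out each replicate in turn gave 3579 to 3987 higher and 4102 to 4658 lower features. At 2-fold, 2376 to 2459 were higher and 2586 to 2849 lower. Across 162 named genes, followed over 20 alternatives wherever they were tested, 3114 results kept direction and call. Of the rest, 35 kept direction but lost the call and 1 changed direction. Most of these genes were picked as large changes past the threshold on the same arrays, so many kept calls follow from that choice. The share of calls that were higher ran from 44.6% to 48.5% over the other scalings. Counting undifferentiated replicates 1 and 3 as 1 sample gave 3604 higher and 4147 lower features. The glycolysis and integrated stress response lists passed among features detected on all 6 arrays (adjusted p = 0.0182 and 0.0391), without a detection filter (adjusted p = 0.00129 and 0.00524) and with fry. Glycolysis also passed with all probes tested (adjusted p = 0.0275). Without a detection filter the astrocyte, oxidative phosphorylation and lysosome lists passed too (adjusted p = 0.00685, 0.00983 and 0.0463), and with fry 11 lists passed that had not with camera.

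The replicate numbers of the groups were tested for pairing. Deviations of arrays with equal numbers correlated at -0.00107, 0.0464 and 0.0462 across genes. Those with unequal numbers correlated at -0.0491 to 0.0115. All of these are weak, but deviations from means of 3 arrays cannot exclude that equal numbers share a culture or batch. With the replicate number as a block, 3909 features were higher and 4530 lower. The file names no slides, so the slide alternative was not run. Fold changes of dim probes are limited by the signal over background, and 32445 probes were removed as not detected on enough arrays.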

Other observations

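The tests on splits, kept signal, single arrays and detection of HOX genes were chosen only after the results they concern had been seen. Subunits of chromatin remodelling complexes changed in both directions between the groups. In the list of methylation and chromatin factors, 8 of 18 tested members rose, 8 fell and 2 did not pass (median 0.39, camera adjusted p = 0.806). SMARCD3, SMARCC2 and DPF1, subunits of BAF complexes, rose at least 15.8-fold, 6.12-fold and at least 5.57-fold. TET1, a 5-methylcytosine dioxygenase, was at least 5.83-fold lower and PHF10, a BAF subunit of progenitors, at least 1.91-fold lower. ACTL6B, the neuronal form of a BAF subunit, was at least 1.75-fold higher and its counterpart ACTL6A 3.41-fold lower, both named after their values were seen.

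Of 22 HOX genes named on the array, which pattern the hindbrain and spinal cord, 0 were detected on all 3 sorted arrays and 1 on any. Of 17 forebrain and midbrain genes, 2 were detected on all sorted arrays and 4 on any. The undifferentiated arrays were close to this, with 0 HOX genes on all and 2 on any, and 1 forebrain or midbrain gene on all and 4 on any. Fisher's exact test, two-sided, on detection on all sorted arrays gave p = 0.184. Of the 4 such genes tested, 3 rose and 1 fell (camera adjusted p = 0.395). DLX1 and DLX5 were at least 6.65-fold and 5.36-fold higher but varied between the sorted arrays, with log2 signals of 7.43, 9.19 and 6.88 for DLX1 and 7.29, 8.50 and 6.77 for DLX5 on replicates 1 to 3. The list deviated by 0.97 on replicate 2 and -0.85 on replicate 3 (adjusted p = 0.0020 for both against random lists). HESX1, a repressor of early anterior development, was at least 1.52-fold lower. EMX2 also rose (at least 1.97-fold, adjusted p = 0.0208), but not past the threshold without undifferentiated replicate 1 (adjusted p = 0.0600) or 3 (adjusted p = 0.0816), without a detection filter (adjusted p = 0.106) or with those replicates as 1 sample (adjusted p = 0.0710).

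The 3 sorted samples differed from one another more than the undifferentiated ones, with a median SD per gene of 0.231 against 0.149 log2 units. The 0.149 may understate the spread, as undifferentiated replicates 1 and 3 share a name and differed by 1.28 times the bead noise. The other undifferentiated pairs differed by SDs of 0.285 and 0.305, and sorted pairs by 0.368 to 0.480. Sorted arrays also had fewer detected probes. The deviation of each of 30 fixed lists on each sorted array was set against 10000 random lists matched on expression, and 24 of 90 comparisons passed after adjustment. Random lists treat genes as independent, so these p-values are too small. Mitotic genes deviated by 0.37 on replicate 1 and -0.41 on replicate 2 (adjusted p = 0.0020 for both, the smallest the random lists gave). The oligodendrocyte progenitor list moved the same way (0.14, adjusted p = 0.0055, and -0.17, adjusted p = 0.0020), as did the G1/S list (0.17, adjusted p = 0.0352, and -0.24, adjusted p = 0.0020). On replicate 3 the astrocyte and the neural stem and radial glia lists were low (-0.46 and -0.34), and so were the forebrain and midbrain, Wnt, mesenchymal, extracellular matrix and cholesterol lists (-0.85, -0.30, -0.27, -0.12 and -0.09), while the neuron and oxidative phosphorylation lists were high (0.16 and 0.10). No explanation of these differences was tested. A list of 14 tested NRF2 targets, written after HMOX1 and NQO1 had been seen, deviated by -0.51 on replicate 1 and 0.45 on replicate 2.

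The split of the 6 arrays into their groups gave 8519 called features. Among all 10 splits into 3 and 3, 1 gave as many, the real one, and the highest of the others gave 0 with limma (10 to 47 at an unadjusted p under 0.05). With 10 splits the share cannot fall under 0.05. The other splits each mix arrays of both groups, so a large group difference widens their spread and few calls follow by construction.

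A few pluripotency genes stayed detectable in the sorted cells. JARID2, SFRP2, TERF1 and PODXL, of which the first 3 were named after their values were seen, are the falling members detected on all sorted arrays. They kept 19.2%, 19.6%, 6.36% and 3.98% of their undifferentiated signal after the offset was removed, a median of 12.8% (SD over the sorted arrays 2.13). Undifferentiated cells carried through the O4 sort would leave every such gene the same share, and LIN28A, detected on no sorted array, allows at most 0.672%. Such cells may be present below that bound. The 4 genes were picked as detected on all sorted arrays, so shares above the bound were largely fixed in advance and are no test of such cells. The LIN28A bound alone limits what such cells could add to 0.672% of each gene's undifferentiated signal. Expression of these genes in the sorted cells themselves was not tested.

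The 21 tested neuronal genes had a median log2 fold change of 2.12, with 17 higher and 2 lower. Neurons that passed the O4 sort are a candidate source. On no sorted array were 12 of the 34 list genes detected, among them RBFOX3, SLC17A6 and SLC17A7, named after their values were seen. Undetected members were not particular to this list. Not detected on enough arrays to be tested were 13 of the 34, against 10 of 31 myelin and 12 of 42 progenitor genes. RBFOX3 marks mature neurons, and SLC17A6 and SLC17A7 mark glutamatergic ones, so their absence does not exclude neurons of other kinds. The 2 probes of GAD1, a marker of GABAergic neurons also named after its values were seen, gave log2 fold changes of 2.09 and 2.12. Neurons and expression in the oligodendrocyte lineage cannot be told apart without a sample of either cell type.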
